A study of Mus musculus with 47 samples.

How the data were processed

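The RNA of 4 brain regions of female mice aged 90 to 92 days was sequenced on an Illumina HiSeq instrument at 4 stages of the estrous cycle. All proestrus libraries came from mice aged 91 days and all estrus libraries from mice aged 90 days. Age and stage therefore coincide in estrus minus proestrus, and only the metestrus libraries held both of these ages. Per the labels, the hippocampus libraries were made with another protocol and those of the other 3 regions with a NEBNext Ultra kit, spike-in RNA was added, and 6 to 9 libraries shared a lane, though the lane of each library is not given in the sources used here. The submitters' processing notes name Trimmomatic 0.32, TopHat2 2.0.8, SAMtools, DESeq 1.12.1 and Cufflinks 2.1.1, with the genome builds GRCm38 and mm10. The program that counted reads per gene and the annotation release are not given in the sources used here. The values deposited by the authors are raw counts per gene, in 37315 Ensembl genes for each region, without normalization. GENCODE M21 gave symbols, coordinates and gene types for 35449 of them, and the other 1866 kept their identifiers. All 47 count columns were used, and 1 further estrus library of the neocortex was not analysed here. The tables held no spike-in genes.

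Within each region, stage was fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with TMM normalization, after filterByExpr (minimum count 10, minimum total 15) by stage. The stage effect was an F-test with 3 degrees of freedom, and 6 pairwise contrasts came from the same fit. P-values were adjusted by Benjamini-Hochberg over all genes of a test, with a threshold of 0.05. The interaction of stage and region had 9 coefficients and used all 47 libraries. Regions were compared with glmTreat against an absolute log2 fold change of 1, with stage as a covariate. The 31 gene lists were tested in each pairwise contrast with camera of limma 3.58.1 (preset correlation 0.01) where at least 3 members passed the filter, with an estimated correlation, and with fry, and p-values were adjusted over lists and contrasts within a region. Members were also counted when adjusted over the list alone. Stability used 95% intervals from limma voom. Variance shares and principal components used log2 CPM with a prior count of 2, and 100 permutations of the stage labels. CPM values are means and SD over libraries, and the floors cover counting error only, since reads without molecular identifiers are not independent molecules.

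The comparisons, tests, gene lists, most alternative analyses and the rule for named genes were fixed before the data were examined. The rule names genes called in the stage or pairwise tests, up to 3 members of each list with the smallest p, a fixed set of hormone, receptor, activity and control genes, up to 10 genes per region with the highest fold change over the 3 other regions, and the 10 genes with the smallest interaction p. Wnt7b, Lars2, and genes called only under an alternative or without 1 library were named after their values were seen. Some genes that the rule names are not reported here. The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, a mean CPM of at least 1, limma voom with sample quality weights or treat, age as a factor, the replicate number as a block, an interval of 0.5, a prior count of 0.5, variance shares without the hippocampus, and leaving out each library in turn. A small RNA covariate and a fit without 2 hypothalamus libraries rich in Lars2 were added after the data were seen. The labels do not say that libraries of the same number come from 1 animal, and samples were treated as unpaired. If equal stage and number mark 1 animal, the main interaction and region fits left that sharing between regions out.

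The procedure was tested on simulated data with changed genes. The stage test recovered 60.7% of genes changed 2-fold in the hypothalamus, 67.7% in the hippocampus, 88.1% in the neocortex and 89.1% in the cerebellum, and 23.9%, 16.4%, 55.7% and 55.2% of genes changed 1.5-fold. Of its calls, 8.22 to 9.27% were false, above the nominal 5%. The interaction test recovered 41.8% of genes changed 2-fold. Each simulation changed 200 genes at once, in estrus libraries only, by 1.5, 2 or 4-fold. With fewer changed genes the adjustment over all genes is stricter and fewer of them would be recovered. The simulated genes also varied independently of each other. For both reasons these shares may overstate the sensitivity in the real libraries. For the real libraries, uniform p-values would put 761.5, 854, 796 and 744 genes under 0.05 in the same order of regions. The stage test put 234, 251, 894 and 256 there, fewer in all but the neocortex. The 46 pairs of replicates of the same stage and region were checked, and 0 were identical.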

Results

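Messenger RNA of the hypothalamus, hippocampus, neocortex and cerebellum was sequenced from adult female C57BL/6J mice, an inbred laboratory strain, at 4 stages of the estrous cycle (proestrus, estrus, metestrus and diestrus). There were 47 libraries, 3 for each stage in the hypothalamus, hippocampus and cerebellum and 11 in the neocortex, where 2 estrus libraries were analysed. The total count per library, in units of 1000000 counts, ranged from 1.83 to 8.26 in the hypothalamus and from 7.67 to 15.68 in the hippocampus. It ranged from 6.31 to 10.54 in the neocortex and from 2.56 to 8 in the cerebellum. Stage and depth were not balanced. In the same units, the mean total was 2.77 in the estrus hypothalamus and 5.43 in the proestrus hypothalamus. It was 7.47 in the estrus cerebellum and 4.25 in the proestrus cerebellum. Xist, the RNA that coats the inactive X chromosome, lay between 419 and 1553 CPM (counts per 1000000 counts of the library) in all 47 libraries, and Ddx3y, on the Y chromosome, had 0 counts in all of them. Kdm5d and Eif2s3y, also on the Y chromosome, had 0 counts as well, while Uty, another gene there, had up to 18 (Hippocampus Estrus 1).

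The series asks how stable the brain transcriptome is over the estrous cycle. Region accounted for 78.3% of the variance in log2 CPM over 18152 genes and stage for 1.44%. Stage labels permuted over the 12 combinations of stage and number gave stage shares of 1.36 to 1.92%, at least as large as the real share in 94 of 100 permutations. The first 3 principal components, with 38.5%, 27.1% and 13.0% of the variance, separated the 4 regions, and region accounted for at least 98.9% of the variance of each.

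**Figure D1:**
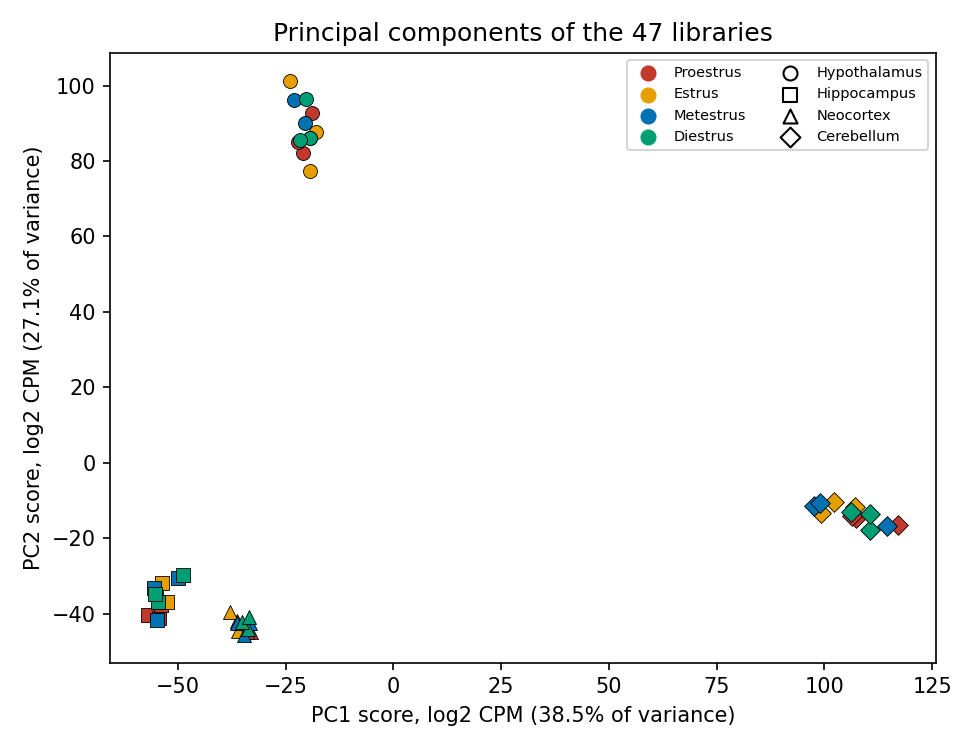
Principal component scores of the 47 libraries, from log2 CPM. Each point is a library, colour gives the stage and shape the region, and the libraries form groups by region, with PC1 holding 38.5% and PC2 27.1% of the variance.

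In the hypothalamus, the stage comparison asks whether any gene differs among the 4 stages. Prl, which encodes the pituitary hormone prolactin, had 65, 55 and 78 counts in the 3 metestrus libraries and 0 in the other 9, so that its level was at least 188-fold higher in metestrus (floor of 3 counts over the other libraries). Gh, growth hormone, had 19, 17 and 46 counts in metestrus and 0 elsewhere, at least 78.0-fold higher with the same floor. Without Metestrus 3 these bounds were 138-fold for Prl and 41.5-fold for Gh. The floors cover counting error only. The hormone and receptor genes of the reproductive axis did not pass the test. Oxt, oxytocin, was at 89.3 CPM ± 6.11 (SD, n = 3) in proestrus and 148 CPM ± 44.7 (SD, n = 3) in estrus. Avp, vasopressin, was at 196 CPM ± 13.2 (SD, n = 3) and 254 CPM ± 23.5 (SD, n = 3). Pomc, the precursor of melanocortins and beta-endorphin, was at 51.97 CPM ± 12.8 (SD, n = 3) and 57.3 CPM ± 12.1 (SD, n = 3). Esr1, the estrogen receptor alpha gene, lay between 26.2 and 28.7 CPM in all 4 stage means, and Pgr, the progesterone receptor gene, between 17.0 and 25.7 CPM.

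No gene of 15230 passed an adjusted p of 0.05 in edgeR's stage test (234 genes had an unadjusted p under 0.05), and limma voom with sample quality weights and DESeq2 called 0. Prl had the smallest adjusted p (edgeR, 0.0509) and Gh an adjusted p of 0.99998. In the 6 pairwise contrasts edgeR and DESeq2 called 0 genes, with 2226 results at an unadjusted p under 0.05 in edgeR summed over contrasts, and limma voom with sample quality weights called 1, Prl, in metestrus minus proestrus. Prl passed the stage test when Estrus 1 (adjusted p = 0.0388), Metestrus 1 (adjusted p = 0.0374) or Metestrus 3 (adjusted p = 0.00944) was left out. DESeq2 gave Prl and Gh an adjusted p of 1 with their dispersion at that tool's upper limit of 12, as it did for no other gene that passed the low-count filter in this region, so its 0 calls are not informative for these 2 genes.

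Of 31 gene lists, 30 could be tested in the hypothalamus. Immediate early genes, which respond quickly to neuronal activity, were higher in estrus than in proestrus in 25 of 27 members (median log2 difference 0.52; camera adjusted p = 1.26e-07 with the preset correlation and adjusted p = 0.968 with an estimated correlation). The list was at -0.46 in Proestrus 3 against -0.20 and -0.12 in Proestrus 1 and 2 (mean log2 CPM relative to the regional mean), and without Proestrus 3 camera called it higher than in proestrus in 1 of 3 contrasts instead of 3. Oligodendrocyte and myelin markers were higher in estrus than in proestrus in 18 of 18 members (median 0.68; camera adjusted p = 4.48e-11 with the preset correlation and adjusted p = 0.968 with an estimated correlation). This list was lowest in Proestrus 3 (-0.51) and highest in Estrus 3 (0.55), close to Estrus 2 (0.53), while Estrus 1 was at -0.12. Estrus 3 also had the highest striatal (1.21) and lowest ependymal (-0.54) marker scores of the region and the highest score on its first principal component. Within these lists, Fos was at 14.1 CPM ± 6.98 (SD, n = 3) in proestrus and 24.8 CPM ± 9.37 (SD, n = 3) in estrus. Mbp, a myelin protein gene, was at 1346 CPM ± 268 (SD, n = 3) and 2374 CPM ± 515 (SD, n = 3). Pituitary markers were higher in metestrus than in proestrus in 6 of 8 members (median log2 difference 0.17, camera adjusted p = 7.60e-04 with the preset correlation and adjusted p = 0.775 with an estimated correlation). The mean log2 difference was 2.17, far above the median, with Prl alone at 9.44, so the rise was not shared evenly by the list. Of the 8 tested, 3, with Prl and Gh among them, were called when adjusted over the list alone, against 0 over all genes. Striatal, ependymal, meningeal, mitochondrially encoded and hippocampus marker lists made up the other camera calls. Camera called 22 of 180 tests, of which 0 were called with an estimated correlation (6 at an unadjusted p under 0.05) or by fry. Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 13.5% of the counts in Estrus 3 and 10.6% in Metestrus 3 against a regional median of 4.13%, and without these 2 libraries Prl was called with an adjusted p of 0.00623 and 32 list tests were called. Estrus 3 was also the least deep library of the region. It had the highest shares of counts in unmatched identifiers (14.8%, median 3.61%) and small RNAs (2.72%, median 0.359%), so its list scores may reflect library quality.

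**Figure D2:**
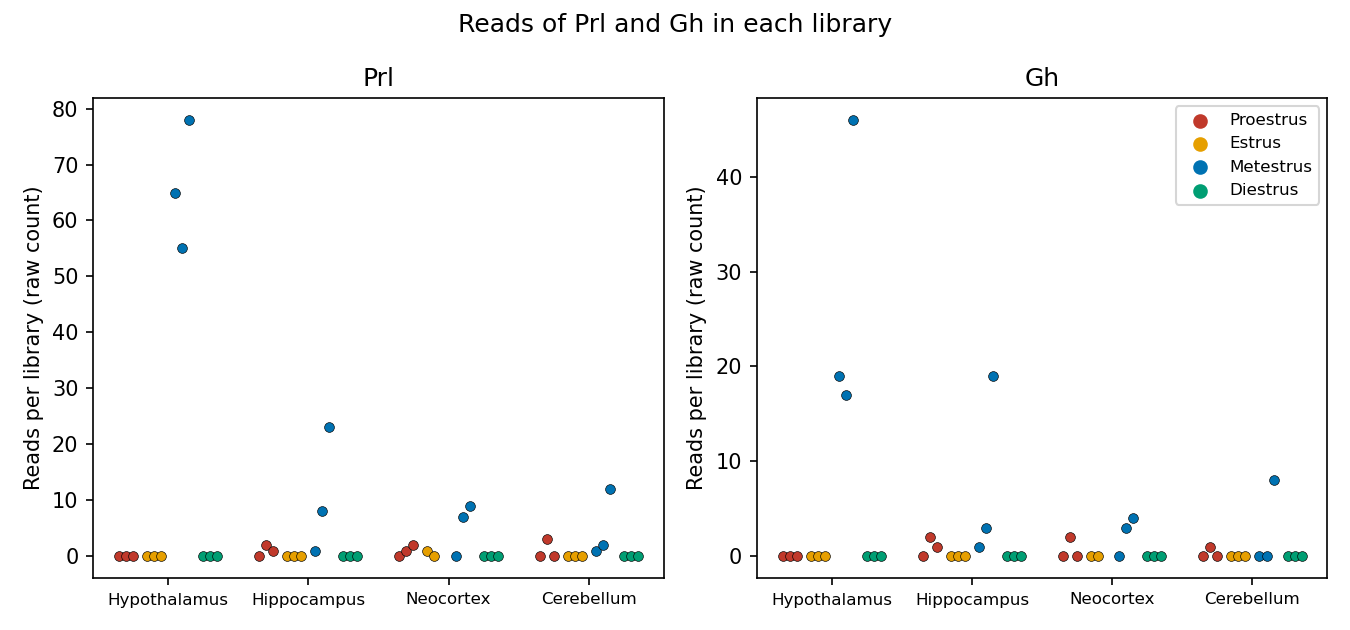
Raw counts of Prl and Gh in each library, by region, with colour giving the stage. Each point is a library. In the hypothalamus the 3 metestrus libraries hold 55 to 78 Prl counts and 17 to 46 Gh counts and the other 9 hold 0, and the highest library of each other region is Metestrus 3.

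In the hippocampus, edgeR called no gene in the same comparison, and list tests with a preset correlation called activity and choroid plexus genes. Immediate early genes were higher in metestrus than in proestrus in 27 of 28 members (median log2 difference 0.43; camera adjusted p = 3.81e-22 with the preset correlation and adjusted p = 0.302 with an estimated correlation). The list was at -0.79 in Proestrus 3, -0.17 in Proestrus 1 and 0.15 in Proestrus 2, and without Proestrus 3 camera called it higher than in proestrus in 1 of 3 contrasts instead of 3. Npas4, an activity-regulated transcription factor gene, was at 8.57 CPM ± 3.71 (SD, n = 3) in proestrus and 16.4 CPM ± 2.51 (SD, n = 3) in metestrus. Choroid plexus markers were higher in diestrus than in proestrus in 20 of 20 members (median 1.13; camera adjusted p = 6.08e-16 with the preset correlation and adjusted p = 0.512 with an estimated correlation). Ttr, transthyretin, the main secreted product of the choroid plexus, was at 1022 CPM ± 790.0 (SD, n = 3) in proestrus and 2265 CPM ± 617 (SD, n = 3) in diestrus. The choroid plexus list was lowest in Proestrus 2, at -2.89 relative to the regional mean. Microglia markers were lower in metestrus than in proestrus (median -0.14; camera adjusted p = 1.24e-04 with the preset correlation and adjusted p = 0.302 with an estimated correlation), with the highest score in Proestrus 1 (0.18). Endothelial and pericyte markers were higher in estrus than in proestrus (median 0.18; camera adjusted p = 3.70e-06 with the preset correlation and adjusted p = 0.160 with an estimated correlation). Proestrus 2 was the lowest library for this list (-0.14) and for choroid plexus, ependymal (-1.03), meningeal (-0.70) and blood cell (-0.67) markers. Esr1 was at 2.12 CPM ± 0.545 (SD, n = 3) in proestrus and 3.20 CPM ± 0.470 (SD, n = 3) in diestrus. Bdnf, brain-derived neurotrophic factor, was at 53.1 CPM ± 7.74 (SD, n = 3) and 46.998 CPM ± 4.53 (SD, n = 3). Gabrd, the delta subunit of the GABA-A receptor, was at 21.8 CPM ± 0.522 (SD, n = 3) and 18.6 CPM ± 0.466 (SD, n = 3).

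Of 17079 genes tested, edgeR called 0 in the stage test (251 at an unadjusted p under 0.05), limma voom with sample quality weights 0, and DESeq2 3, which were Gm15716, Klk14 and Pigr. In the 6 pairwise contrasts edgeR called 0 (2039 at an unadjusted p under 0.05, summed over contrasts), DESeq2 1 and limma voom with sample quality weights 7. Camera called 43 of 186 list tests, of which 0 were called with an estimated correlation (18 at an unadjusted p under 0.05) or by fry. The other called lists were those of glucocorticoid-responsive, glutamate receptor and postsynaptic density, interferon-stimulated, heat shock, estrogen-responsive and sex check genes, mitochondrially encoded transcripts, and meningeal, ependymal, striatal, hypothalamus, hippocampus and cerebellum markers. Adjusted over the list alone, 1 of 4 tested pituitary markers, Pou1f1, was called, at 1.16 CPM ± 0.553 (SD, n = 3) in metestrus and 3.23 CPM ± 0.302 (SD, n = 3) in diestrus, against 0 over all genes.

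In the neocortex, where estrus had 2 libraries, the lists with the most members called on their own were immediate early genes, striatal markers and clock genes. Adjusted over the list alone, 8 of 28 immediate early genes, 3 of 18 clock genes, 2 of 38 glutamate receptor and postsynaptic density genes, 1 of 15 astrocyte markers, 6 of 14 striatal markers and 1 of 12 hippocampus markers were called, against 0 over all genes. The smallest such adjusted p of the immediate early genes was 0.0496 (edgeR stage test), so their 8 calls all lay just under the threshold. Adjustment over a list alone does not cover the number of lists and regions. Per2, a core clock gene, was at 36.5 CPM ± 7.65 (SD, n = 3) in proestrus and 21.5 CPM ± 5.09 (SD, n = 2) in estrus. Homer1, a postsynaptic scaffold gene, was at 324 CPM ± 57.2 (SD, n = 3) in diestrus and 186 CPM ± 12.1 (SD, n = 2) in estrus. Bdnf was at 53.7 CPM ± 6.91 (SD, n = 3) and 37.8 CPM ± 0.241 (SD, n = 2). Immediate early genes were higher in diestrus than in proestrus in 26 of 28 members (median log2 difference 0.37; camera adjusted p = 1.41e-11 with the preset correlation and adjusted p = 0.992 with an estimated correlation), and without Proestrus 3, at -1.10, camera called it higher than in proestrus in 1 of 3 contrasts instead of 2. Arc was at 489.6 CPM ± 252 (SD, n = 3) in proestrus and 719 CPM ± 34.99 (SD, n = 3) in diestrus. Clock genes were lower in estrus than in proestrus in all but 2 of 18 members (camera adjusted p = 0.00104 with the preset correlation and adjusted p = 0.950 with an estimated correlation). The clock list was at -0.20 in Estrus 1, its lowest library, and -0.12 in Estrus 2, and Estrus 1 was also its lowest library in the hippocampus (-0.12) and cerebellum (-0.15). In the neocortex Estrus 1 was the lowest library for glucocorticoid-responsive genes (-0.33) and the highest for striatal markers (0.83). Striatal markers were higher in estrus than in proestrus in 14 of 14 members (median 0.37; camera adjusted p = 1.45e-05 with the preset correlation and adjusted p = 0.950 with an estimated correlation). Adora2a, the adenosine A2a receptor gene of striatal neurons, was at 8.53 CPM in Estrus 1 and 1.72 CPM in Estrus 2.

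Of 15926 genes, edgeR called 0 in the stage test (894 at an unadjusted p under 0.05), limma voom with sample quality weights 0 and DESeq2 4. In the pairwise contrasts edgeR called 0 (5454 at an unadjusted p under 0.05, summed over contrasts), limma voom with sample quality weights 0 and DESeq2 65, of which 58 were in diestrus minus estrus. The smallest adjusted p of the stage test was 0.702 (edgeR, Wnt7b, a secreted Wnt ligand gene). Camera called 23 of 180 list tests, of which 0 were called with an estimated correlation (6 at an unadjusted p under 0.05) or by fry, and 8 without Estrus 1. The other called lists were glucocorticoid-responsive genes, cholesterol synthesis genes, nuclear-retained long noncoding RNAs, and microglia, meningeal, oligodendrocyte and neocortex markers. Leaving out Estrus 1 or Estrus 2 left a single estrus library, so a call in either fit cannot be told from a trait of that library. The call of Adora2a without Estrus 2, where only Estrus 1 remained, is of this kind.

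**Figure D3:**
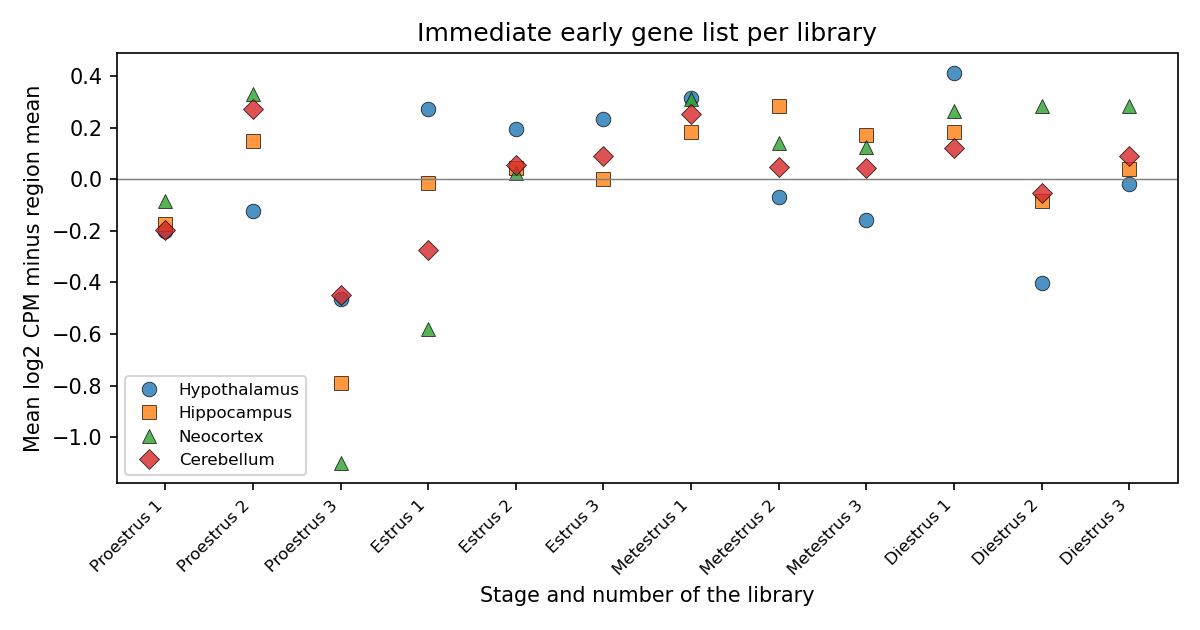
Mean log2 CPM of the immediate early gene list in each library relative to its regional mean, by stage and number, with shape and colour giving the region. The Proestrus 3 libraries are the lowest of all 4 regions, at -0.46, -0.79, -1.10 and -0.45 in the hypothalamus, hippocampus, neocortex and cerebellum.

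In the cerebellum, the genes called when adjusted over a list alone mark other brain areas. Tcf7l2, a transcription factor gene of thalamic neurons, was at 27.8 CPM ± 17.1 (SD, n = 3) in metestrus and 6.66 CPM ± 0.443 (SD, n = 3) in diestrus, with 37.3, 38.2 and 8.11 CPM in Metestrus 1, 2 and 3 and 21.6 CPM in Estrus 2. Adjusted over the list alone, Tcf7l2 was called among 15 tested thalamic markers and Baiap3 among 3 tested hypothalamus markers, against 0 over all genes. Glucocorticoid-responsive genes were higher in diestrus than in estrus in 16 of 18 members (median log2 difference 0.23; camera adjusted p = 8.47e-04 with the preset correlation and adjusted p = 0.947 with an estimated correlation). This list was highest in Diestrus 1 in all 4 regions, at 0.66 in the hypothalamus, 0.37 in the hippocampus, 0.42 in the neocortex and 0.44 in the cerebellum, where Diestrus 2 and 3 were at -0.14 and -0.05. It was lowest in Estrus 1 in the hypothalamus, hippocampus and neocortex. Interferon-stimulated genes were higher in diestrus than in proestrus in 12 of 14 members (median 0.28; camera adjusted p = 2.84e-04 with the preset correlation and adjusted p = 0.947 with an estimated correlation). Proestrus 1, the least deep cerebellum library, was the lowest for this list (-0.38) and for the glucocorticoid-responsive (-0.45), ependymal (-0.98) and microglia (-0.27) lists, and stood apart on the first principal component of the region. Meningeal and fibroblast markers were higher in diestrus than in metestrus in 17 of 18 members (median 0.30; camera adjusted p = 2.23e-07 with the preset correlation and adjusted p = 0.947 with an estimated correlation), and this list was lowest in Metestrus 3, at -0.47. Gabrd lay between 137 and 148 CPM in the 4 stage means.

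Of 14877 genes, edgeR, DESeq2 and limma voom with sample quality weights each called 0 in the stage test (256 at an unadjusted p under 0.05 in edgeR) and 0 in the 6 pairwise contrasts (2074 at an unadjusted p under 0.05 in edgeR, summed over contrasts). Without Metestrus 3, edgeR called 5 genes in the stage test, Fam163b, Lhx9, Tcf7l2, Enc1 and Nrgn, and 10 in diestrus minus metestrus. Camera called 12 of 174 list tests, of which 0 were called with an estimated correlation (5 at an unadjusted p under 0.05) or by fry, and 25 without Metestrus 3. The other called lists were immediate early genes and oligodendrocyte, astrocyte and choroid plexus markers. In all 4 regions camera called 0 tests of steroid and prolactin receptors and coregulators, neurosteroid and estrogen synthesis, reproductive-axis and hypothalamic neuropeptides, GABA receptor and inhibitory synapse genes, proliferation and neurogenesis genes, and blood cell and thalamic markers, and fry called 0 as well.

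The interaction of stage and region asks whether stage differences differ between regions. Tcf7l2, Pigr, which encodes the polymeric immunoglobulin receptor, Pax2, a developmental transcription factor gene, and Nrgn, a postsynaptic calmodulin-binding protein gene, were among the 10 genes with the smallest p. The test of 18152 genes gave 0 calls in edgeR (276 at an unadjusted p under 0.05, smallest adjusted p = 1) and 1 in DESeq2. Without Cerebellum Metestrus 3, edgeR called 3.

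Stability was measured as the share of genes whose 95% intervals (limma voom) lay within 1 log2 unit in all 6 stage pairs, which bounds a change at less than 2-fold. This held for 76.0% of genes in the hypothalamus, 78.4% in the hippocampus, 83.4% in the neocortex and 84.2% in the cerebellum. The share depends on the width of the intervals, so a gene that was not bounded is not shown to change. Depth and spread differed between the regions, so these shares do not rank them by stability. In the most abundant 25% of genes the shares were 98.5%, 98.5%, 99.5% and 99.6%, and in the least abundant 25% they were 19.3%, 27.4%, 36.5% and 39.7%. Esr1 was bounded at -0.59 to 0.58 in the hypothalamus, whereas Oxt (-1.18 to 1.19), Fos (-1.19 to 2.09) and Pgr (-1.13 to 0.89) were not. All 25 tested GABA receptor and inhibitory synapse genes and all 24 cholesterol synthesis genes were bounded in the hypothalamus, against 8 of 27 immediate early genes, 4 of 18 oligodendrocyte and myelin markers and 1 of 18 meningeal markers. In the hippocampus Gabrd (-0.51 to 0.50), Bdnf (-0.49 to 0.43) and Mbp (-0.37 to 0.31) were bounded, and 0 of 20 choroid plexus markers were. In the neocortex 24 of 24 cholesterol synthesis genes and 6 of 28 immediate early genes were bounded, and in the cerebellum 20 of 20 cerebellum markers were.

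The region comparisons give the scale against which stage differences can be read. In the hypothalamus, Pmch, melanin-concentrating hormone (ENSMUSG00000035383, chromosome 10, 88091072 to 88092375 on GRCm38), was at 211 CPM ± 59.3 (SD, n = 12) in the hypothalamus and 0.173 CPM ± 0.195 (SD, n = 11) in the neocortex, the next region (log2 fold change 10.08 ± 0.23, SE). Avp (ENSMUSG00000037727, chromosome 2, 130580620 to 130582554) was at 207 CPM ± 43.4 (SD, n = 12) and exceeded the hippocampus by 8.91 ± 0.16, and Oxt (ENSMUSG00000027301, chromosome 2, 130576173 to 130577054) was at 109.5 CPM ± 36.7 (SD, n = 12) and exceeded it by 8.58 ± 0.20. Nr5a1, Nkx2-4, Six6, Otp, the orexin gene Hcrt and Parpbp, which overlaps Pmch, were also among the 10 genes that stood highest over the 3 other regions. In the cerebellum the granule cell gene Gabra6 (ENSMUSG00000020428, chromosome 11, 42306437 to 42321072) was at 403 CPM ± 37.3 (SD, n = 12) against 0.174 CPM ± 0.517 (SD, n = 12) in the hippocampus (11.03 ± 0.21), and Fat2, an atypical cadherin gene, at 923 CPM ± 102 (SD, n = 12) (10.56 ± 0.24). Cnpy1, Crtam, Tlx3, Cbln3, Sycp1, Lbx1, Hes3 and Iltifb followed.

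The neocortex had smaller differences from its nearest region, with Xirp2 (5.22 ± 0.36 over the hippocampus), Dkkl1 (4.82 ± 0.16) and Mei1 (4.47 ± 0.25) at the top, and Cd6, Myl4, Gm11549, Igfn1, Trbc2, Krt80 and Trbc1 behind. In the hippocampus Lrrc17, a leucine-rich repeat gene, was at 196 CPM ± 131 (SD, n = 12) against 0.658 CPM ± 0.519 (SD, n = 12) in the hypothalamus (8.12 ± 0.35), and the 10 genes that stood highest also included the small nucleolar RNAs Snord49a (9.08 ± 0.39) and Snord55 and the pseudogene Tpt1-ps6. The hippocampus libraries were made with another protocol, so that region and protocol cannot be separated in its contrasts. Of the fixed marker lists, 18 of 18 tested hypothalamus markers, 11 of 20 hippocampus markers, 9 of 20 neocortex markers and 20 of 20 cerebellum markers were called higher in their own region than in each other region. The neocortex list included Bcl11b, which exceeded the neocortex in the hippocampus, at 274 CPM ± 36.5 (SD, n = 12) against 85.1 CPM ± 5.81 (SD, n = 11).

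Of 16529 genes, edgeR called those with an absolute log2 fold change over 1 at an adjusted p under 0.05. There were 2320 between hypothalamus and hippocampus (1030 higher in the hypothalamus), 2667 between hypothalamus and neocortex (1520 higher), 3051 between hypothalamus and cerebellum (1976 higher), 1249 between hippocampus and neocortex (860 higher in the hippocampus), 3130 between hippocampus and cerebellum (2100 higher) and 2829 between neocortex and cerebellum (1688 higher in the neocortex). Higher than in all 3 other regions were 496 genes in the hypothalamus, 284 in the hippocampus, 170 in the neocortex and 504 in the cerebellum. Without a filter on low counts the calls were 3824 between hypothalamus and hippocampus, 2673 between hippocampus and neocortex and 5021 between hippocampus and cerebellum.

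Esr1 was at 27.03 CPM ± 4.18 (SD, n = 12) in the hypothalamus and 2.70 CPM ± 0.643 (SD, n = 12) in the hippocampus, and Prlr, the prolactin receptor gene, at 57.04 CPM ± 11.3 (SD, n = 12) and 77.6 CPM ± 34.1 (SD, n = 12). The hippocampus libraries were made with another protocol, and their choroid plexus marker scores ranged from -2.89 to 0.93. These levels therefore do not settle which region expresses more Prlr. Esr2, Gnrh1 and Cyp19a1, the genes of estrogen receptor beta, gonadotropin-releasing hormone and aromatase, had too few counts to be tested in any of the 4 regions, with 46, 18 and 1 counts over the 12 hypothalamus libraries. A stage difference in them was not detectable at this depth. Kiss1 was not analysed here.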

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

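The small RNA covariate, the fit without the 2 hypothalamus libraries over 10% Lars2 and the splits of the calls without a low-count filter were chosen after the results were seen. No region fold change reversed in sign, and a reversal could be scored only for these. Under the alternatives 1717 values stayed the same, 164 moved and 17 grew stronger. Those that stayed the same include counts that held no calls in either fit. With RLE factors, no count of calls changed by more than 1.5 times. Spike-in scaling was not run, because the tables held no spike-in genes.

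DESeq2 called 3 genes in the stage test of the hippocampus and 4 in the neocortex, where edgeR called 0. In its pairwise contrasts it called 1 in the hippocampus (diestrus minus metestrus) and 65 in the neocortex (58 in diestrus minus estrus and 7 in estrus minus proestrus), and 1 in the interaction. Limma voom with sample quality weights called 1 in the hypothalamus (metestrus minus proestrus) and 7 in the hippocampus (diestrus minus estrus). Age as a factor gave 1 call in the neocortex, Mid1, in metestrus minus proestrus. The cause was not tested for these. For Prl and Gh in the hypothalamus, DESeq2's dispersion was at its upper limit of 12, against trend values of 0.0974 and 0.193. Its adjusted p of 1 is therefore not informative for them. The adjusted p of Prl over 20 alternatives ranged from 3.05e-31 to 1 (to 0.172 without DESeq2) and passed in 7, and that of Gh from 1.75e-16 to 1 and passed in 1.

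With the replicate number as a replicate block, Prl was called in the hypothalamus (adjusted p = 0.00908), giving 1 call in the stage test and 2 over the pairs, 1 in metestrus minus proestrus and 1 in diestrus minus metestrus. The numbers were checked before blocking. Same-numbered libraries of the same stage in different regions had a median residual correlation of 0.0266, with 12 of 69 pairs over 0.1, against -0.0113 and 14 of 138 for other-numbered ones. Of 47 libraries, 26 correlated best with their own number in other regions, against 15.7 by chance, so the numbers may mark shared animals. Within a region, same-numbered libraries of other stages had 11 of 69 pairs over 0.1, against 23 of 138 for other-numbered ones. Only this within-region comparison bears on the replicate block, and it gave no sign that equal numbers share a source across stages. With the small RNA covariate the hypothalamus stage test called 1, Prl. Without the 2 libraries over 10% Lars2 it called 1, and the pairs 2, 1 each in metestrus minus proestrus and diestrus minus metestrus.

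Without a low-count filter, the stage test called 115 genes in the hypothalamus, 0 in the hippocampus, 169 in the neocortex and 81 in the cerebellum, and 9 in the interaction, and the pairs 221, 0, 497 and 165. In the order estrus minus proestrus, metestrus minus proestrus, diestrus minus proestrus, metestrus minus estrus, diestrus minus estrus and diestrus minus metestrus, the calls were 88, 10, 1, 14, 67 and 41 in the hypothalamus, 131, 23, 21, 91, 226 and 5 in the neocortex, and 27, 33, 10, 38, 27 and 30 in the cerebellum. Of the stage calls, 110, 168 and 77 pass the filter, and the prior degrees of freedom of the spread rose from 8.11 to 144 in the hypothalamus and from 11.7 and 9.48 to infinity in the neocortex and cerebellum. Of 100 splits of the libraries, the real one included, 76 gave as many calls in the hypothalamus (highest other 608), 34 in the neocortex (1108) and 99 in the cerebellum (555). Chance therefore cannot be excluded for these calls. With 0 calls in the hippocampus all 100 splits gave as many (2206). Without the filter the region calls were 3824 (hypothalamus against hippocampus), 2673 (hippocampus against neocortex) and 5021 (hippocampus against cerebellum).

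An estimated correlation or fry left 0 list calls in each of the 4 regions, against 22, 43, 23 and 12. An interval of 0.5 bounded 35.1%, 38.0%, 54.4% and 53.9% of genes in the hypothalamus, hippocampus, neocortex and cerebellum, a tighter bound by construction. A mean CPM of at least 1 gave 70.7%, 82.1%, 86.2% and 80.7%, and variance shares of 81.8% for region and 1.21% for stage. A prior count of 0.5 gave 72.4% and 1.87%, and leaving out the hippocampus 80.5% and 1.77%.

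Leaving out each library in turn gave 0 to 1 stage calls in the hypothalamus, 0 to 1 in the neocortex and 0 to 5 in the cerebellum, and 0 to 3 in the interaction (3 without Cerebellum Metestrus 3). The hypothalamus call was Prl, without Estrus 1, Metestrus 1 or Metestrus 3, and without Metestrus 3 the pairs gave 2 calls, 0 to 1 each in metestrus minus proestrus and diestrus minus metestrus. In the hippocampus the pairs gave 0 to 1 (Gm10250 in diestrus minus estrus, without Diestrus 3). In the neocortex they gave 0 to 4, with 4 in diestrus minus estrus without Proestrus 3 and 1 without Diestrus 2, 0 to 3 in diestrus minus proestrus (3 without Diestrus 3), 0 to 2 in estrus minus proestrus (2 without Proestrus 2) and 0 to 1 in metestrus minus estrus (without Estrus 2). The neocortex fits without Estrus 1 or Estrus 2 left a single estrus library, so their calls do not rest on replicates of that stage. In the cerebellum the pairs gave 0 to 10, the 10 in diestrus minus metestrus without Metestrus 3. List calls ranged from 13 to 31 in the hypothalamus, 34 to 45 in the hippocampus, 8 to 28 in the neocortex and 8 to 25 in the cerebellum. Bounded shares ranged from 63.7 to 73.7%, 73.0 to 76.2%, 77.0 to 82.5% and 78.5 to 82.2% in the same order of regions, each lower than with all libraries.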

Other observations

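The tests of pituitary tissue in the dissection, of library depth and of the immediate early genes were chosen only after the result was seen. Xist was lowest in Diestrus 3 in all 4 regions, an observation made after its values were seen, at 582 CPM in the hypothalamus, 421 CPM in the hippocampus, 419 CPM in the neocortex and 644 CPM in the cerebellum, against regional medians of 1309, 854, 698 and 1052 CPM. Markers of tissues that border the regions varied widely between libraries. Choroid plexus markers fell to -2.92 in Cerebellum Metestrus 3 (mean log2 CPM relative to the regional mean), meningeal markers to -2.49 in Hypothalamus Metestrus 3, and striatal markers reached 1.21 in Hypothalamus Estrus 3.

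The first pattern was Prl and Gh in the 3 metestrus hypothalamus libraries, for which depth of the libraries is argued against, since 1 metestrus library was less deep than the regional median. A prediction written before the Prl and Gh counts of the other regions were read, though the pituitary list scores of those regions had been seen, was that pituitary RNA carried into all tissues of the metestrus animals would put most of their Prl and Gh counts into metestrus libraries, and 86.3% of the 117 counts lay there, against 24.0% of all counts, with the highest raw count in Metestrus 3 of each region. They were not even over the metestrus numbers, with 75 in Metestrus 3, 23 in Metestrus 2 and 3 in Metestrus 1, against 11 in Proestrus 2, so carry-over of pituitary RNA may account for the counts of Metestrus 3 but was little seen in Metestrus 1. Pituitary tissue in the hypothalamus dissection stays open, because Cga, which encodes the common subunit of pituitary glycoprotein hormones, differed by 0.659 CPM, less than its spread between libraries of 2.44 CPM in metestrus and 1.81 CPM in the other stages, and Pitx1 differed by -0.289 CPM. In Metestrus 3, Cga had 0 counts and Pitx1 1, while Pomc was the highest of its region in the hypothalamus (95.8 CPM), hippocampus (4.77 CPM) and neocortex (3.31 CPM), and a stage difference in expression stays open as untested.

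The second pattern was a low level of the immediate early gene list in Proestrus 3 of all 4 regions, at -0.46 in the hypothalamus, -0.79 in the hippocampus, -1.10 in the neocortex and -0.45 in the cerebellum. Camera called the list higher than in proestrus in 9 of 12 contrasts and in 3 of 12 without Proestrus 3. Estrous stage is argued against as the whole cause, since both other proestrus libraries lay below the median of the other stages in 1 region, and depth of the libraries is too, since Proestrus 3 was the least or most deep library in 1 region. A state of 1 animal shared by its regions may account for it if equal numbers mark 1 animal, which the labels do not state. Without Proestrus 3, libraries of equal stage and number still deviated together across regions (mean Pearson r = 0.505, one-sided permutation p = 0.000540; mean Spearman rho = 0.449, permutation p = 0.00870; mean r = 0.483, permutation p = 0.0135, without Proestrus 1 and Estrus 1 as well).

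The third pattern was the number of low p-values in the 3 estrus contrasts of the neocortex, 4312 at an unadjusted p under 0.05, summed over contrasts. Striatal tissue in the Estrus 1 library was a candidate source, from a prediction written before the refit, and 3014 remained without Estrus 1 against 3023 without Estrus 2, or 99.7%. Either library left a single estrus sample, which is assumed to vary like the others, and the test did not decide. The list of striatal markers, 14 of which were tested, stood at 0.83 in Estrus 1 and -0.01 in Estrus 2. Estrous stage stays open.

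All counts of splits given here include the real one. As many genes at an unadjusted p under 0.05 in the stage test came from 95 of 100 splits of the hypothalamus (real 234, highest other 1440), 75 of the hippocampus (251, 4527), 27 of the neocortex (894, 2611) and 92 of the cerebellum (256, 1572). Summed over the pairwise contrasts, 94 (2226, 7338), 83 (2039, 17954), 24 (5454, 10883) and 95 splits (2074, 7944) gave as many, and in the interaction 53 of 60 (276, 2506). Chance cannot be excluded for any of these counts. Some splits gave several times the real count, and the cause was not tested. List calls were as many in 79 (22, 44), 52 (23, 45) and 92 splits (12, 44) of the hypothalamus, neocortex and cerebellum, and in 4 of the hippocampus (43, 49). The hippocampus was the only 1 of 4 regions examined to fall under the 5% level, so chance is not excluded over the 4. In the hippocampus 0 of those calls held with an estimated correlation. For the region contrasts, 1 of 60 splits, the real one, gave as many calls in each of the 6, with highest other counts of 0 (hypothalamus against hippocampus, 2320), 428 (hypothalamus against neocortex, 2667), 3 (hypothalamus against cerebellum, 3051), 338 (hippocampus against neocortex, 1249), 62 (hippocampus against cerebellum, 3130) and 0 (neocortex against cerebellum, 2829). No other split drawn reached the real count in any of the 6, though 60 splits cannot show a share under 1 of 60.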
